A study of Homo sapiens with 3 samples.

How the data were processed

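ChIP-seq of HA-tagged TFE3 was carried out in HK-2 cells that express HA-TFE3 under doxycycline control. Per the labels' protocols, culture lasted 24 h in the presence or absence of doxycycline at 0.2 µg/ml, the chromatin was digested enzymatically with a commercial kit, and complexes were precipitated with an anti-HA matrix. The labels do not state which libraries came from doxycycline-treated cells, so no statement about induction is made. Samples were grouped by their titles into 2 HA-TFE3 ChIP replicates and 1 input DNA library.

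For each ChIP library the authors deposited a list of 1 bp summits, each with a peak name and a score. The score is the authors' own value of each summit and is used only to describe and rank summits within a list. Its scale is not given in the sources used here. The lowest scores, 1.31 and 1.32, lie just above 1.301, the negative decimal logarithm of 0.05, but no label gives that meaning. The peak names are numbered per library without a gap, as if each list was called on its own library, but no label states this. The coordinates are on hg19, per the submitters' processing notes. The aligner, the peak caller, their settings and the use of the input library as a background are not given in the sources used here. A peak caller's threshold and the depth of a library both set how many summits are listed, so the number of summits is not a measure of how much TFE3 was bound.

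Positions were converted to 1-based coordinates. Summits on chromosomes 1 to 22 and X were used, which left out 35 summits of replicate 1 and 45 of replicate 2. Summits of the 2 lists were paired when each was the nearest of the other and they lay at most 100 bp apart. Chance sharing was measured with 100 circular shifts of one list by random distances along each chromosome, and with shifts of 5 kb in each direction. A score percentile is the rank of a summit in its own list. Shares carry exact (Clopper-Pearson) binomial intervals and densities exact Poisson intervals, all at 95%. These intervals cover counting error only, and neighbouring summits are not independent. Shares of shared and single-library summits were compared with two-sided Fisher's exact tests in each library, and densities in light and dark bands with a two-sided exact sign test over chromosomes.

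Cytogenetic bands and their staining classes came from the hg19 band table of circlize 0.4.16, and chromosome lengths from GenomeInfoDb 1.38.1. The band ends equalled the chromosome lengths on all 23 chromosomes. Random placements kept each shared summit in its own band and were drawn 100 times. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.

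The pairing and density steps were tested on simulated lists of 60000 summits that shared 45000 with a known displacement and had a known 3-fold density in unstained bands. The pairing recovered 99.97% of the shared summits and the density step gave 2.98-fold. Independent simulated lists shared 303 summits, against 232.8 after circular shifts.

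The rule for the summits and regions named in the report was set before the data were examined. It takes the 20 shared summits with the highest mean score percentile, of which 10 are given with positions, and the 5 windows of 100 kb with the most shared summits. Base 197463915 of chromosome 3 and the pairs on chromosome 19 were added after their values were seen, as were the named bands and empty stretches. The comparison of staining classes and of bands was also chosen after seeing the data. No gene annotation or sequence of hg19 was used here. The planned analyses of genomic location, of gene lists and of sequence motifs at summits were therefore not run, and no summit is assigned to a gene. The alternatives tried were limits of 50, 200 and 500 bp between shared summits, the summits scoring above the median of each list, the 10000 highest-scoring summits of each list, each library alone, quintiles in place of deciles, and chromosome lengths without centromeres, variable heterochromatin and stalks.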

Results

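Binding of HA-tagged TFE3 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in HK-2 cells, an established line derived from human kidney proximal tubule epithelium. TFE3 is a basic helix-loop-helix leucine zipper transcription factor of the MiT/TFE family, whose members are known to control lysosomal and autophagy genes. The cells carried an HA-TFE3 gene that doxycycline switches on, and chromatin was precipitated through the HA tag. The series holds 3 samples, of which 2 are replicate HA-TFE3 ChIP libraries and 1 is input DNA. Each ChIP library was represented by a list of binding summits, single bases that the authors listed with a peak name and a score. A bound region may hold several summits. The input library entered no comparison. The labels do not say which libraries came from doxycycline-treated cells, and no control for the precipitation was analysed here, so its background was not measured. The 2 ChIP libraries are separate samples in the labels, but nothing says that they came from separate cultures, so the spread between them may be technical.

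The list of replicate 1 held 62322 summits and that of replicate 2 held 72692. On chromosomes 1 to 22 and X, 62287 and 72647 of them were used. Replicate 2 thus had 10360 more summits than replicate 1 over these chromosomes. The scores ran from 1.31 to 270.2 with a median of 8.55 in replicate 1, and from 1.32 to 253.2 with a median of 8.38 in replicate 2. The median distance to the next summit was 13098 bp in replicate 1 and 11303 bp in replicate 2. Sequencing depth is unknown, because the lists give no read counts.

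The first question was how many HA-TFE3 summits were found in both libraries. Within 100 bp and pairing each summit once, 47396 summits were shared. They made up 76.1% of replicate 1 (95% exact binomial interval 75.8 to 76.4) and 65.2% of replicate 2 (64.9 to 65.6), 2 shares that differ only through the lengths of the lists. The median distance between the paired summits was 26 bp, and 882 pairs lay on the same base. No pair had both the same base and the same score. When one list was moved along each chromosome by a random distance, 345.3 ± 22.3 summits were shared (SD over 100 shifts), and the highest of the shifts gave 421. The observed number was 137-fold above this chance level. Shifts of 5 kb up or down, which keep the local density of summits, left 912 and 892 shared summits, so the observed number was 52.5-fold above them. With a limit of 50 bp the shared part of replicate 1 was 60.3%.

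The scores of the shared summits were related between the libraries. Spearman's rank correlation was 0.729 across the 47396 pairs, and Pearson's r of the log2 scores was 0.742. These are correlations across summits, which are not independent replicates, so no p-value is given.

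The shared summits with the highest scores are given by chromosome and base in replicate 1 on hg19. The highest score of each library belonged to the same pair, at base 566206 of chromosome 1 in band 1p36.33, with 270.2 in replicate 1 and 253.2 in replicate 2. The second pair lay in the same band at base 567398, with scores of 214.9 and 203.7. Next were base 110076591 of chromosome 13 in 13q33.3 (148.7 and 145.8) and base 79947342 of chromosome 5 in 5q14.1 (137.1 and 134.0). Chromosome 5 also held base 134262762 (131.1 and 108.5) and base 134263451 (95.7 and 99.8), both in 5q31.1. Base 10531189 of chromosome 11 in 11p15.4 scored 125.5 and 117.4, and base 88124455 of chromosome 2 in 2p11.2 scored 111.4 and 104.4. The first 10 pairs were completed by base 50561344 of chromosome 12 in 12q13.12 (87.7 and 110.8) and base 45291633 of chromosome 7 in 7p13 (96.5 and 97.3). Of the 20 pairs with the highest mean score percentile, 15 lay in unstained cytogenetic bands, which held 57.5% of all shared summits. Another 1 lay in 6q11.1, a band that holds a centromere. The lowest scores among the 20 pairs were 72.5 in replicate 1 and 79.0 in replicate 2. The other 10 included base 197463915 of chromosome 3 in 3q29, the same base in both libraries, and 2 pairs on chromosome 19, in 19q13.33 and 19q13.42. The mitochondrial genome itself also carried 1 summit in each library, with scores of 211.0 and 217.1. Whether the named pairs are binding sites or places where reads collect without binding was not tested. With a limit of 50 bp, the pair in 12q13.12 and 2 more of the 20, in 1q44 and 10q26.13, no longer counted as shared.

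Summits found in both libraries were compared with those found in 1. Shared summits had higher scores within their own list. Their median score percentile was 59.1 in replicate 1, against 24.8 for the 14891 summits without a partner. In replicate 2 it was 64.3, against 27.4 for 25251 summits without a partner. The difference was 34.3 percentile points in replicate 1 and 36.9 in replicate 2. Of the summits without a partner, 80.6% in replicate 1 and 81.3% in replicate 2 scored below the median of their list. Shared summits also lay slightly more often in light cytogenetic bands, meaning the unstained bands and those of 25% stain. In replicate 1 the share was 69.4% against 67.3% (odds ratio 1.10, 95% interval 1.06 to 1.15, two-sided Fisher's exact p = 1.94e-06). In replicate 2 it was 69.4% against 68.0% (odds ratio 1.07, interval 1.03 to 1.10, two-sided Fisher's exact p = 0.000112). Both tests used the same shared pairs, so they are not independent of each other. Neighbouring summits are not independent either, so these p-values describe the lists. The comparison of light bands was not made at equal scores.

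The share of summits found in the other library rose with the score. In replicate 1 it was 44.8% in the lowest decile of scores (95% interval 43.5 to 46.0) and 94.1% in the highest (93.5 to 94.7). In replicate 2 it was 26.5% in the lowest decile (25.5 to 27.6) and 94.6% in the highest (94.1 to 95.1). The increase from one decile to the next stopped above decile 9 in replicate 1, at 94.5%. The highest decile also held the largest share of summits in light bands, 74.3% in replicate 1 and 73.8% in replicate 2. In the lowest decile this share was 68.2% and 68.5%. It did not rise steadily, and was smallest in decile 5 of replicate 1 (66.1%) and decile 2 of replicate 2 (65.8%).

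**Figure D1:**
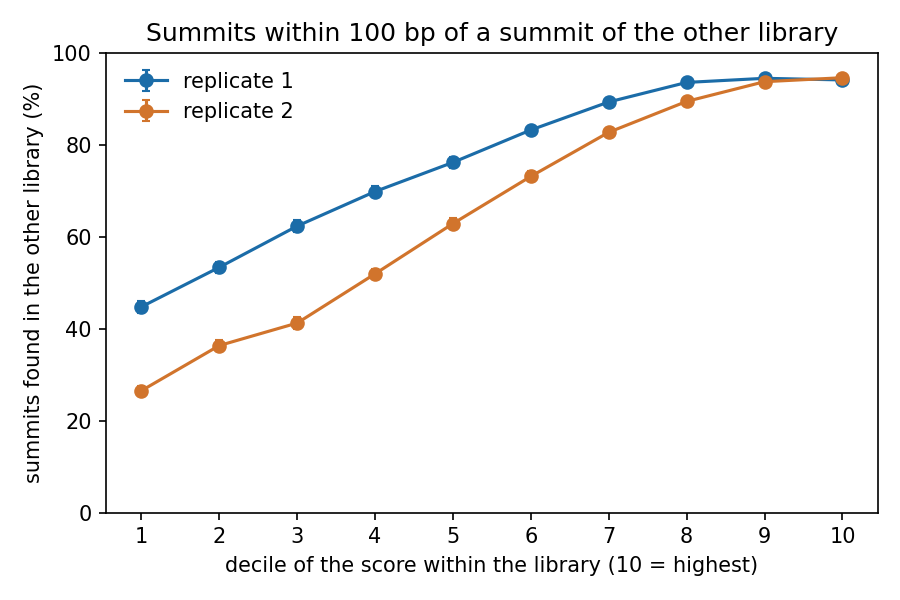
Percent of each library's summits that had a summit of the other library within 100 bp (vertical axis), by decile of the score within the library (horizontal axis, 10 the highest); points are shares and bars are 95% exact binomial intervals. Replicate 1 runs from 44.8% to 94.1% and replicate 2 from 26.5% to 94.6%.

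The next comparison asked where along the genome HA-TFE3 summits were dense. Shared summits occurred at 15.6 per Mb over all chromosomes used. Chromosome 19, known as the most gene-rich human chromosome, was the densest, with 40.1 shared summits per Mb (95% Poisson interval 38.5 to 41.7). Chromosome 17 followed with 33.9 per Mb, chromosome 20 with 25.1, chromosome 22 with 23.3 and chromosome 1 with 21.6. Chromosome X had 6.51 shared summits per Mb (6.12 to 6.93) and chromosome 13 had 6.56 (6.10 to 7.04). Chromosomes 21, 18 and 5 had 8.77, 8.81 and 10.3 per Mb. These densities use full chromosome lengths. With centromeres, variable heterochromatin and stalks left out, chromosome 22 had 35.3 per Mb, level with chromosome 17 at 35.4 and above chromosome 20 at 26.7. Chromosome 21 then had 12.4 per Mb, above chromosomes 5 and 18 at 10.5 and 9.14, and chromosomes 19, 13 and X had 49.1, 7.89 and 6.69. The density of shared summits on chromosome 19 was 6.16-fold that on chromosome X. Among the 10000 highest-scoring summits of each list it was 14.5-fold. The number of copies of each chromosome in these cells was not measured, so the densities are not corrected for it.

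Relative to each library's own genome average, the density of all its summits on chromosome 19 was 2.52 ± 0.064 (SD, n = 2). It was 2.09 ± 0.017 on chromosome 17, 0.448 ± 0.003 on chromosome 13 and 0.443 ± 0.008 on chromosome X. The SD between the libraries was at most 0.064 on any chromosome, so these differences were larger than the spread between replicates. Chromosome 11, at 0.830 ± 0.0065, had a lower density than chromosomes 10 and 12, at 1.14 ± 0.023 and 1.17 ± 0.015. Among the 10000 highest-scoring summits of each list, the relative density of shared summits was 3.997 on chromosome 19 and 0.196 on chromosome 13, against 2.57 and 0.420 over all shared summits. It was 0.276 on chromosome X, 0.282 on chromosome 21 and 0.289 on chromosome 18, against 0.417, 0.562 and 0.565. For all summits, as means of both libraries, chromosomes 2 and 3 lay at the genome average, with 1.002 and 1.001.

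**Figure D2:**
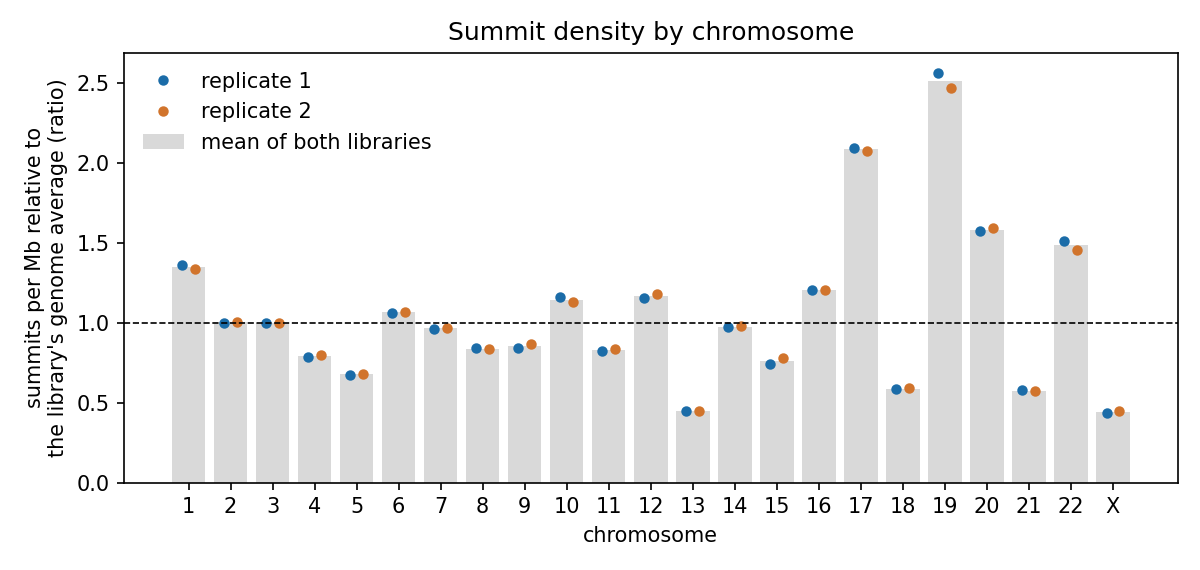
Summits per Mb on each chromosome divided by the library's genome average (vertical axis, a ratio); bars are means of the libraries, points are replicate 1 and replicate 2, and the dashed line marks the average. Chromosomes 19 and 17 stand at 2.52 and 2.09, and chromosomes X and 13 at 0.443 and 0.448.

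HA-TFE3 summits were concentrated in lightly staining bands. Giemsa staining divides chromosomes into light bands, known to be rich in genes and early replicating, and dark bands that hold few genes. Unstained bands had 21.2 shared summits per Mb (95% Poisson interval 20.9 to 21.4) and bands of 25% stain had 25.9 (25.2 to 26.6). The density then fell with the stain, to 15.2 per Mb at 50%, 11.2 at 75% and 7.14 (6.91 to 7.38) at 100%. Unstained bands held 57.5% of the shared summits on 42.4% of the length, and bands of 100% stain held 7.51% on 16.4% of the length. Bands that hold centromeres had 1.76 shared summits per Mb, and those of variable heterochromatin held 127 shared summits in 98.0 Mb. No shared summit lay in the 23.2 Mb of acrocentric stalks. How much of these last classes can be mapped was not measured here.

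Unstained bands had 2.96-fold the density of bands of 100% stain for shared summits, 2.87-fold for all summits of replicate 1 and 2.81-fold for replicate 2. Of the 18 chromosomes with both kinds of band, 18 had the higher density of shared summits in the unstained bands (two-sided exact sign test over chromosomes, p = 7.63e-06). The fold within a chromosome ran from 1.95 on chromosome 18 to 4.91 on chromosome X.

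**Figure D3:**
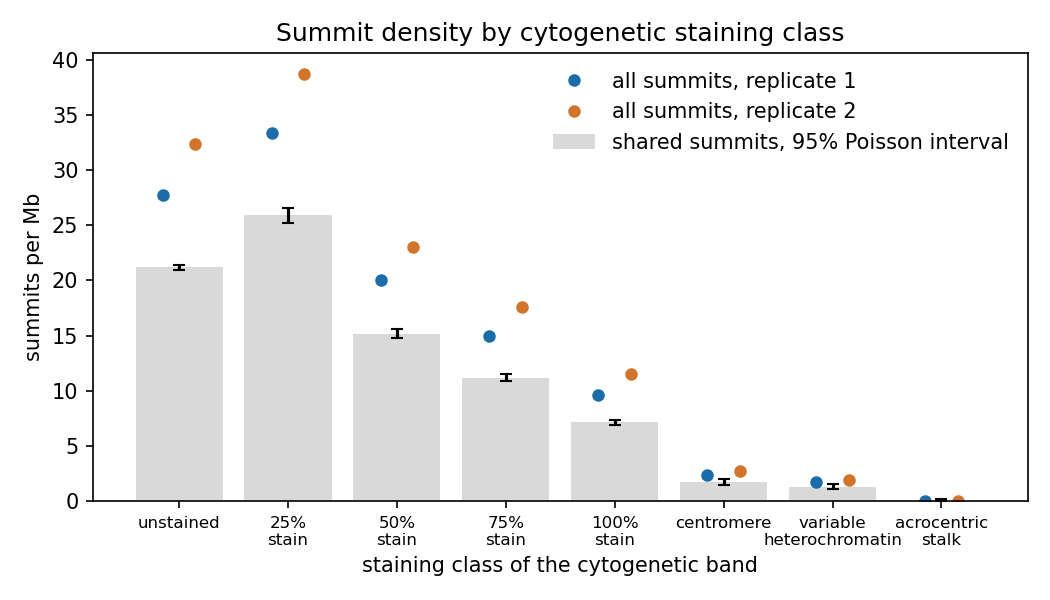
Summits per Mb (vertical axis) in each staining class of cytogenetic bands (horizontal axis); bars are shared summits with 95% Poisson intervals and points are all summits of replicate 1 and replicate 2. Shared summits fall from 25.9 per Mb at 25% stain to 7.14 at 100% stain.

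Among bands of at least 1 Mb outside centromeres and heterochromatin, 6p21.33 was the densest. This band, which is part of the major histocompatibility complex region, held 142 shared summits, or 83.5 per Mb (95% Poisson interval 70.4 to 98.5). Band 19q13.32 held 210 shared summits in 2.8 Mb (65.2 to 85.9 per Mb) and 1q22 had 69.3 per Mb (56.7 to 84.0). Bands 9q34.11, 19q13.33, 17q21.2 and 19p13.3 had 65.6, 65.3, 65.2 and 63.6 per Mb. The interval of 6p21.33 lay above that of 19p13.3 (57.8 to 69.9) but overlapped those of the other named bands. These were 57.0 to 75.1 for 9q34.11, 57.0 to 74.5 for 19q13.33 and 55.6 to 76.0 for 17q21.2, besides the intervals of 19q13.32 and 1q22 given above. Differences between the named bands were not tested. Relative to the genome average, the first 3 stood at 5.35, 4.80 and 4.44, and at 8.77, 7.42 and 8.13 among the 10000 highest-scoring summits of each list.

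Shared summits also gathered in shorter windows. The 100 kb window with the most of them was bases 300001 to 400000 of chromosome 20 in 20p13, with 25 shared summits, 28 summits in replicate 1 and 31 in replicate 2. Bases 74000001 to 74100000 of chromosome 10 in 10q22.1 held 23 shared summits, as did bases 76300001 to 76400000 of chromosome 17 in 17q25.3. Bases 43200001 to 43300000 of chromosome 17 in 17q21.31 and bases 30600001 to 30700000 of chromosome 22 in 22q12.2 held 20 each. The mean was 1.56 per window, and 49.3% of the 30376 windows held none. Among the summits above the median score of each list, these 5 windows held 15, 12, 13, 7 and 11 shared summits, and among the 10000 highest-scoring summits they held 6, 6, 3, 3 and 6. With a limit of 50 bp the window in 17q21.31 held 13. When the shared summits were placed at random within their own bands, the fullest window held 16.4 on average and 23 at most over 100 placements. The window on chromosome 20 lay above that highest value, and those on chromosome 10 and in 17q25.3 equalled it. The windows with 20 lay below it but above the average. In the actual list, 8.71% of distances from a shared summit to the next were at most 1 kb. Under random placement the share was 2.54% ± 0.07 (SD over 100 placements). Random placement spreads summits evenly over whole bands, so several summits within the same bound region would also give such an excess.

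Other stretches held no shared summit. The longest one outside centromeres and heterochromatin ran over 7.65 Mb of chromosome X, from base 86664659 to 94314047 in Xq21.31 to Xq21.33, where replicate 1 had 0 summits and replicate 2 had 3. The second, in 21q21.1 and 21q21.2, covered 4.19 Mb of chromosome 21 from base 22572671 to 26758402, with 1 summit in replicate 1 and 7 in replicate 2. Stretches of 3.95 Mb in Xq27.3, 3.90 Mb in 8p23.2 and 3.81 Mb in Xp21.3 followed. How much of these stretches can be mapped was not measured, so an empty stretch is not shown to lack binding.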

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

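The test of the highest-scoring summits was chosen only after the result was seen. A summit on the mitochondrial genome, which the comparisons of the report do not use, appeared in each list with a score far above most nuclear summits. It scored 211.0 in replicate 1, at base 9908, and 217.1 in replicate 2, at base 10038. The medians of all summits were 8.55 and 8.38, so these scores were 24.7 and 25.9 times the median. The input library was not used here, so there is no background value for this signal.

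A candidate explanation for the highest-scoring nuclear summits is that mitochondrial reads were placed on nuclear copies of mitochondrial DNA. The stretch of chromosome 1 that holds the first 2 pairs is known as background to contain a long nuclear copy. Whether the other named pairs lie on such copies was not checked here. Under this explanation the mitochondrial summit ranks high in both lists, and a rank below 1000 in either would have argued against it. Its rank was 3 in replicate 1 and 2 in replicate 2, and the lower of these, 3, does not separate mitochondrial reads placed on nuclear copies from strong binding of HA-TFE3. The sequences under the summits would be needed to tell them apart. No biological explanation was tested.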

How the results depend on the processing

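The comparisons of light and dark bands, the chromosome lengths without centromeres, heterochromatin and stalks, and the top deciles of each library by arm, were chosen after seeing the data. No fold, odds ratio, difference or correlation changed direction, and no relative density crossed the genome average. The order of some chromosomes and bands did change. With the shortened lengths, chromosome 22 rose above chromosome 20 in relative density (2.11 and 1.59, against 1.49 and 1.61). Chromosome 21 rose above chromosome 5 (0.738 and 0.629, against 0.562 and 0.659). Among the 10000 highest-scoring summits, chromosome 13 fell below X (0.196 and 0.276, against 0.420 and 0.417). It also did so above the median score (0.328 and 0.364). At limits of 50, 200 and 500 bp chromosome 13 had 0.394, 0.425 and 0.426, and X had 0.400, 0.431 and 0.432. With each library alone and with the shortened lengths, chromosome 13 stayed above X. The fold of unstained over darkest bands stayed past the test's threshold under the 7 alternatives run, between 2.81 and 4.11, and the odds ratios of light bands did so under the 5 run, between 1.07 and 1.15 in replicate 1 and between 1.05 and 1.14 in replicate 2. The difference in sharing between the highest and lowest score class of replicate 1, 49.4 points, stayed within the spread between libraries, quintiles included. That of replicate 2, 68.1 points, did so except among the 10000 highest-scoring summits, where it was 54.3. This spread is the SD between the libraries, whose differences lie far apart, so it is a wide limit. The alternatives gave 41.5 to 53.8 points in replicate 1. Among other results, 137 values moved past their limit, the spread between libraries or a fixed fold for 100 kb window counts, and 113 did not. Score percentiles of the named summits change by construction when the lists are shortened.

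The shared part of replicate 1 was 60.3% at 50 bp, 80.3% at 200 bp, 81.9% at 500 bp, 77.8% among summits above the median score and 67.2% among the 10000 highest-scoring summits, against 76.1% as reported. For replicate 2 it was 51.7%, 68.9%, 70.2%, 65.9% and 67.2%, against 65.2%. A wider limit pairs more summits by construction. The Spearman rank correlation of the scores was 0.739 at 50 bp, 0.677 above the median score and 0.568 among the 10000, against 0.729, and the last 2 sets have a narrower range of scores. The difference in median percentile in replicate 1 was 27.7 at 50 bp, 36.2 at 200 bp, 36.9 at 500 bp, 31.4 above the median score and 32.0 among the 10000, against 34.3. Chance sharing was 902.0 with a 5 kb shift, against 345.3. The density on chromosome 19 over that on X was 6.42-fold at 50 bp, 8.32-fold above the median score and 14.5-fold among the 10000, against 6.16-fold, and 5.51 to 5.86-fold with each library alone. For the other moves the cause was not tested. The alternatives planned for genomic location, gene lists and motifs were not run. No paired analysis was possible because the files hold 1 group. Depth could not be weighed without read counts.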

Other observations

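All tests in this part were chosen after the results had been seen. The strength of HA-TFE3 summits differed between chromosome arms in a way that the report has not described. Strong summits are here the 10% of shared summits with the highest mean score percentile. On 19q they made up 19.4% of the shared summits (95% exact binomial interval 17.2 to 21.8), on 20q 15.6%, on 19p 14.9%, on 1q 13.6%, on 20p 13.5% and on 3q 13.4%. On 8p they made up 2.65% (1.46 to 4.41), on 21q 3.59%, on 18q 4.21%, on 13q 4.24% and on 10p 4.29%. The top decile of each library taken alone gave 4.37% and 5.13% of the summits on 8p, and 18.9% and 17.6% on 19q.

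On chromosomes 3, 8 and 10 the short arms held few strong summits. Chromosome 3 had 5.28% strong summits on the short arm and 13.4% on the long arm. In 10 Mb windows the values on its short arm lay between 0.0% and 8.43%, and those on its long arm between 6.52% and 16.4%. The long arm exceeded the short arm in light bands of chromosome 3 by 2.70-fold (95% interval 1.87 to 3.89, two-sided Fisher's exact, Benjamini-Hochberg adjusted over 6 tests, p = 8.55e-09) and in darker bands by 2.15-fold (1.33 to 3.48, Fisher's exact adjusted p = 0.00138). On chromosome 8 the ratios were 3.10 in light bands (1.68 to 5.72) and 4.69 in darker bands (1.46 to 15.1), the last resting on 3 strong summits of 191 on the short arm. On chromosome 10 they were 2.79 (1.64 to 4.74) and 3.47 (1.304 to 9.25). Over all bands the ratio on chromosome 8 was 3.46, and it fell to 2.16 and 1.75 when the top decile of each library was taken alone, while those on chromosomes 3 and 10 stayed between 2.13 and 2.94. These 3 chromosomes were picked for the size of the difference, so the p-values overstate the evidence.

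A candidate explanation is that these cells carry fewer copies of the whole short arms. The first 20 Mb of the long arm should then hold more strong summits than the short arm. The ratio was 2.12 on chromosome 3 (95% interval 1.41 to 3.19), 3.66 on chromosome 8 (1.90 to 7.01) and 1.85 on chromosome 10 (1.01 to 3.39), where the rest of the long arm exceeded these 20 Mb by 1.68-fold (1.10 to 2.55). Because the chromosomes were picked for this difference, the test could exclude the explanation but not bear it out, and it stays open beside untested differences in gene content or chromatin. The number of summits, set against what staining classes predict, was 1.99 times higher on the long arm for chromosome 10, 1.81 for chromosome 3 and 1.05 for chromosome 8, but also 1.85 for chromosome 9 and 0.565 for chromosome 6.

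Some strong summits had no partner in the other library. In the highest score decile these were 363 summits of replicate 1 and 390 of replicate 2. They may be summits placed apart within the same bound region, since the pairing allows only 100 bp. A summit of the other library lay within 500 bp of 97.0% of them in replicate 1 and of 97.4% in replicate 2, at median distances of 142 and 141.5 bp. After shifts of 5 kb the shares were 8.40% and 5.0%. In the lowest decile, by contrast, 26.2% and 17.3% of the summits without a partner had a summit of the other library within 500 bp. Only 11 strong summits of replicate 1 and 10 of replicate 2 had none within that distance. No biological explanation was tested.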
